A study of Mus musculus with 7 samples.

How the data were processed

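The samples were 7 libraries of RNA from eosinophils sorted from mouse muscle, 3 WT and 4 IL5-Tg by the genotype given in the labels. Per the labels' protocols, stranded mRNA libraries were prepared from RNA of cells sorted into RNAzol and sequenced as short paired reads on an Illumina NextSeq. The deposited values are raw read counts per gene symbol, with 1 column per library and no normalization, as seen from their whole numbers and differing totals. Per the submitters' processing notes, bcl2fastq 2.20, Bowtie and STAR were used with the mm10 build. The role and order of these tools, the program that counted reads, the annotation and the strand setting are not given in the sources used here, so reads of overlapping genes, antisense genes and near-identical copies may have been divided in ways that cannot be told from the counts.

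The table held 24421 genes and 2 rows that name no gene. Those rows, for reads assigned to no feature and for ambiguous reads, took 9.15% to 18.2% and 0.750% to 0.943% of each library and were left out of library sizes and tests. Total counts were 18408816, 11581365 and 14294462 in WT replicates 1, 2 and 3, and 12135031, 16416831, 14760825 and 20231509 in IL5-Tg replicates 1, 2, 3 and 4. Replicate numbers were given in accession order and only name a library. Replicate pairs differed by chi-square values per gene of 27.5 to 159, so no library was counted as a repeat of another.

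The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr by group, robust estimation, genotype as the only term and all 7 libraries in the fit. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and a positive log2 fold change means higher in IL5-Tg. CPM values use TMM-scaled library sizes. Standard errors were taken from the fold change and the F statistic. The common biological coefficient of variation was 52.5%. For a gene with 0 WT reads a fold was computed against 3 reads over the group and against 3 molecules of 12 reads, the highest WT value of the most common low count, and for 1 to 3 reads the pooled ratio with an exact binomial 95% interval.

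Before the data were examined, 34 gene lists, the tests and the rule for named genes were fixed. The rule took Il5, the 10 genes with the highest mean CPM, up to 12 called genes per direction by fold change with a standard symbol, groups that do not overlap and a mean of at least 5 CPM in the higher group, and up to 4 called members per list or, where none passed, 2 with the smallest p. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. This left 27 lists, and none of the mitochondrially encoded genes was among the rows. List levels are means of log2(CPM + 1), compared by a two-sided exact permutation test over the 35 splits of 7 libraries into 3 and 4, whose smallest p is 0.0286.

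The procedure was tested on simulated counts for the 12428 tested genes, with 50 genes changed at each of 4 fold sizes. It recovered 6% of genes changed 2-fold, 38% at 4-fold, 74% at 8-fold and 78% at 16-fold, with 4 false calls among 102, and made 1 call where nothing was changed. Changes of 2-fold were therefore mostly below what this design detects. The simulated counts gave a gene the same spread in all libraries, as estimated by the main fit. They did not copy the lower correlations between WT libraries or the differing low counts. The simulation therefore does not give the rate of false calls in the real data.

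Alternatives were RLE and upper-quartile normalization, DESeq2 1.42.0, limma-voom with quality weights, estimation without robustness, other count filters, removal of the 10 most abundant or the sex-linked genes, thinning, a 1.5-fold minimum with glmTreat, the shared start of sample titles as a block, and leaving out each library. Added after seeing the data were the level of other cells' markers as a covariate, division of counts by the most common low count, this division followed by random thinning of all libraries to the smallest total of 965068 molecules, a mean CPM of at least 10, and the newer edgeR fit. The most common low count is the centre of the window of 5 counts that holds most genes. Gene positions are from GENCODE vM21 on mm10, matched by symbol, and 49 of the 51 changed genes had one.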

Results

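RNA sequencing was used to compare eosinophils, granulocytes of type 2 immunity, between muscles of wild-type (WT) mice and of mice labelled IL5-Tg. IL-5 is the cytokine that drives the production and survival of eosinophils, and the series' design text concerns the effect of an excess of these cells on muscle homeostasis, regeneration and repair. Cells were sorted from digested, damaged muscle 3 days after ntx, which the labels do not spell out, as CD45-positive and SiglecF-positive cells that were negative for NK1, Ly6G and CD3e. There were 3 WT and 4 IL5-Tg libraries. Their total counts ranged from 11581365 to 20231509, of which 9665093 to 17447106 were assigned to genes. The labels do not say whether the libraries of a group came from separate mice, so p-values measure the spread between these libraries, and counting intervals and floors cover counting error only. Sequencing does not separate eosinophil RNA from RNA of other sorted cells, so levels of other cell types' markers are given with the results.

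Il5, the gene that gives the IL5-Tg mice their name, was present in every IL5-Tg library and nearly absent from WT libraries. Il5 lies on chromosome 11 at 53720794 to 53725106 on the plus strand (mm10, GENCODE vM21). Its level was 349, 447, 338 and 368 CPM in IL5-Tg replicates 1, 2, 3 and 4. WT replicate 1 had 23 Il5 reads, or 1.39 CPM, and WT replicates 2 and 3 had 0 reads, which allows up to 0.317 and 0.284 CPM by a floor of 3 reads, or 2.53 and 3.40 CPM by a floor of 3 molecules, if 1 molecule gives 8 and 12 reads, the most common low counts there. The group means were 376 ± 49.5 CPM (SD, n = 4) and 0.463 ± 0.802 CPM (SD, n = 3), a log2 fold change of 9.38 ± 1.01 (SE; edgeR adjusted p = 0.00952), or 8.75 to 15.2 over the alternative settings. The labels do not say which cells express the transgene. The RNA of the IL-5 receptor subunit Il5ra was 130 CPM in WT and did not pass the test (log2 fold change -0.97, edgeR adjusted p = 0.363).

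The comparison of all genes asked how eosinophils in the muscle of IL5-Tg mice differed from those in WT muscle. Of 12428 genes tested, 51 changed, 42 higher and 9 lower in IL5-Tg libraries. The most strongly raised genes were almost silent in WT cells. Car4, a membrane-anchored carbonic anhydrase, rose from 1.32 ± 0.639 CPM (SD, n = 3) to 422 ± 129 CPM (SD, n = 4), a log2 fold change of 8.27 ± 0.51 (SE; edgeR adjusted p = 9.8e-05). Adra2a, the alpha-2A adrenergic receptor, had 1 read in all WT libraries together and 92.0 ± 35.5 CPM (SD, n = 4) in IL5-Tg libraries. The ratio of its pooled levels was 3193, with a 95% counting interval from 573 to 126145 that treats reads as independent. Cacna2d2, an auxiliary subunit of calcium channels, had no WT read and was 88.7-fold higher than a floor of 3 reads over the WT group, but only 7.39-fold higher than a floor of 3 molecules of 12 reads each. Against that second floor Adra2a was 88.7-fold higher. Cdkn2a, which encodes inhibitors of the cell cycle, rose from 1.30 ± 1.58 to 72.4 ± 3.36 CPM (SD, n = 3 and 4), by 5.84 ± 0.91 on the log2 scale (SE; edgeR adjusted p = 0.0478).

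Other genes with large increases were Ngp, a granule protein best known from neutrophils (log2 fold change 7.47, from 6 WT reads, all in WT replicate 1, and 6.98 to 11.5 over the alternative settings), Aifm3 (5.97), the uridine phosphorylase Upp1 (5.37), the matricellular protein gene Nov (4.81), the leukotriene B4 receptor Ltb4r2 (3.86), the actin regulator Enah (3.68) and the ion exchanger Slc24a3 (3.62). Enah was already expressed in WT cells and went from 24.6 ± 7.03 to 315 ± 51.6 CPM (SD, n = 3 and 4). Upp1 went from 4.43 ± 2.27 to 182 ± 76.8 CPM.

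Fewer genes fell in the main test, and several of them were abundant. Retnlg, a resistin-like secreted protein and 1 of the 10 most abundant genes, dropped from 9663 ± 742 CPM (SD, n = 3) to 3235 ± 763 CPM (SD, n = 4), a log2 fold change of -1.58 ± 0.27 (SE; edgeR adjusted p = 0.0416). The matricellular protein gene Thbs1 went from 4895 ± 3242 to 1004 ± 187 CPM (log2 fold change -2.29, edgeR adjusted p = 0.0497), and WT replicate 3 alone held 8575 CPM. The chemokine Ccl9 went from 2324 ± 408 to 828 ± 129 CPM. Hdc, the enzyme that makes histamine, went from 296 ± 141 to 52.0 ± 13.6 CPM (log2 fold change -2.51, edgeR adjusted p = 0.0236). Retnlg was also a member of the list of neutrophil markers, and Hdc of the list of mast cell and basophil markers. The other lower genes were Pbld1 (-2.92), the chromatin organiser Satb1 (-2.09), the class I histocompatibility gene H2-Q4 (-1.72), Prr7 (-1.61) and, outside the rule for named genes, 5830416P10Rik (-3.20). Reads of H2-Q4 can be shared with near-identical class I genes, so its split from them is uncertain. The other 9 of the 10 most abundant genes did not pass the test, among them Actb (log2 fold change 0.02) and the chemokine Ccl6 (0.24).

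**Figure D1:**
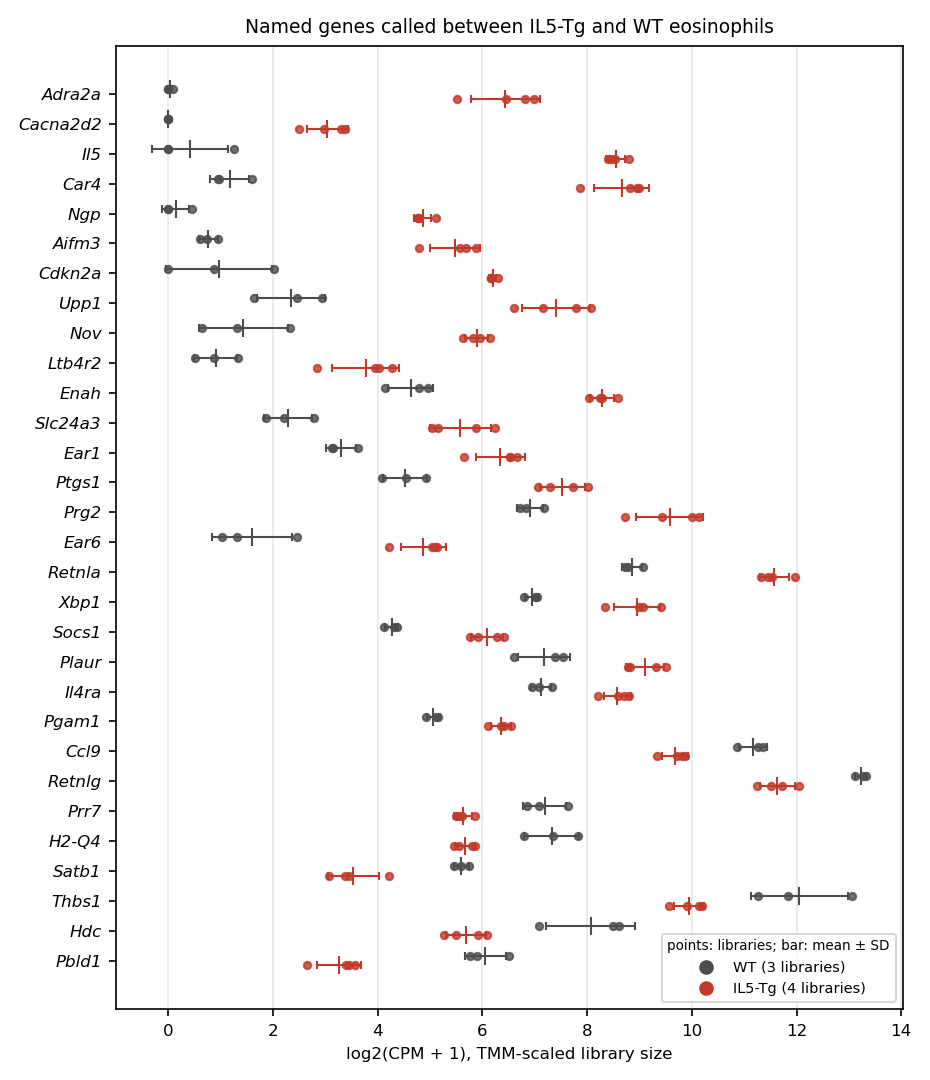
Expression of the named changed genes in each library, as log2(CPM + 1) on the horizontal axis. Points are libraries (3 WT in grey, 4 IL5-Tg in red), and bars give the mean and SD. In every gene shown the 2 groups do not overlap, which the rule for naming genes by fold change required. Il5, for example, lies at 0 to 1.39 CPM in WT and 338 to 447 CPM in IL5-Tg libraries.

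All 51 changed genes had groups that did not overlap, which is no separate support, since the test itself favours such genes. Over all tested genes 1163, or 9.36%, did not overlap, where chance gives 5.71%. The count of changed genes was 19 without WT replicate 1, 61 without WT replicate 2, 97 without WT replicate 3, and 16, 16, 17 and 30 without IL5-Tg replicates 1, 2, 3 and 4. Without WT replicate 2, 30 were higher and 31 lower, and by DESeq2 141 were higher and 84 lower, so the excess of higher genes depends on these choices. Car4, Upp1, Enah, Ear1, Ptgs1 and Retnla passed under every alternative setting in which they were tested.

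Among the gene lists fixed beforehand, eosinophil granule proteins were higher in IL5-Tg libraries by camera (adjusted p = 1.4e-13), though not with an estimated correlation (adjusted p = 0.170). By fry, which tests whether members move on balance in one direction, the adjusted p was 0.0324. Of 6 tested members 3 rose, 3 did not pass and 0 fell, and 5 rose when adjusted over the list alone. Prg2, the major basic protein, rose from 120 ± 21.2 to 815 ± 320 CPM (SD, n = 3 and 4; log2 fold change 2.76 ± 0.37 SE, edgeR adjusted p = 0.0160). The eosinophil-associated ribonucleases Ear1 and Ear6 rose by 3.21 and 3.60 on the log2 scale, but these genes are near-identical copies, so how reads were divided among them is uncertain. The eosinophil peroxidase gene Epx had a log2 fold change of 1.59 (edgeR adjusted p = 0.402) and Prg3 of 0.20.

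Genes linked to IL-5 receptor and STAT5 signalling and survival were higher as a list by camera (adjusted p = 5.7e-06), but not with an estimated correlation (adjusted p = 0.394) or by fry (adjusted p = 0.0816). Over all genes only Socs1, a feedback inhibitor of cytokine receptors, passed, rising from 18.3 ± 1.62 to 68.4 ± 14.4 CPM (SD, n = 3 and 4; edgeR adjusted p = 0.0165). Of 21 tested members 9 were higher and 1 lower when adjusted over the list alone. Values that did not pass over all genes were Socs2 at 3.08 (edgeR adjusted p = 0.0502), Bcl2l1 at 1.79 and Ccnd2 at 1.46, while Mcl1 was at -0.80. Lipid mediator genes were higher by camera (adjusted p = 0.0299) and by fry (adjusted p = 0.0324), with adjusted p = 0.394 by camera with an estimated correlation, 0.0907 without WT replicate 1 and 0.370 without WT replicate 2. In that list only Ptgs1, the constitutive cyclooxygenase, rose over all genes, from 22.6 ± 6.76 to 190 ± 57.0 CPM (log2 fold change 3.08, edgeR adjusted p = 0.00402), and 12 of 13 members did not pass. Ptges3 was at -1.03 and was the 1 lower member when adjusted over the list alone.

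Of the response genes of IL-4 and IL-13, 2 of 11 tested members rose and 9 did not pass. Retnla, a resistin-like protein induced by these cytokines, rose from 465 ± 63.4 to 3086 ± 632 CPM (SD, n = 3 and 4; log2 fold change 2.73 ± 0.28 SE, edgeR adjusted p = 0.00311), and the receptor chain Il4ra from 139 ± 19.4 to 387 ± 66.2 CPM (edgeR adjusted p = 0.0382). The list's camera adjusted p was 0.00015, and adjusted p = 0.394 with an estimated correlation. Retnla and Retnlg, which moved in opposite directions, are related genes on chromosome 16, at 48842551 to 48844461 and 48872621 to 48874496 (mm10, GENCODE vM21). Of the eosinophil receptors and lineage regulators 1 of 15 rose, the transcription factor gene Xbp1, from 123 ± 11.8 to 513 ± 145 CPM (edgeR adjusted p = 0.0172). Siglecf, whose product was used in the sort, was at 0.43 and the eotaxin receptor gene Ccr3 at -0.59, and neither passed. The list's camera adjusted p was 0.0251, and adjusted p = 0.627 with an estimated correlation. It was 0.289, 0.370 and 0.194 without WT replicate 1, WT replicate 2 and IL5-Tg replicate 2.

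Glycolysis and hypoxia genes were higher by camera (adjusted p = 0.00156, and adjusted p = 0.585 with an estimated correlation), and 1 of 25 members passed, Pgam1, at 1.32 (edgeR adjusted p = 0.0424). Lower by camera were cytosolic ribosomal proteins (mean log2 fold change -0.30, camera adjusted p = 0.00015, and adjusted p = 0.627 with an estimated correlation). None of the 51 ribosomal members passed by edgeR, and 0 had a positive log2 fold change. Cytokines and chemokines were lower (camera adjusted p = 0.00156, and adjusted p = 0.585 with an estimated correlation), and Ccl9 alone passed of 26 members. Active tissue eosinophil markers were lower (camera adjusted p = 0.00169, and adjusted p = 0.585 with an estimated correlation), with Thbs1 the 1 member of 15 that passed. Immediate early and dissociation genes were lower (camera adjusted p = 0.0141, and adjusted p = 0.585 with an estimated correlation), and 0 of 20 members passed by edgeR. These calls depended on single libraries. Without WT replicate 1 the cytokine list had a mean log2 fold change of 0.37 (camera adjusted p = 0.249) and the glycolysis list of 0.24 (camera adjusted p = 0.177). The cytokine list's level was 6.23 in WT replicate 1, against 4.99 and 5.37 in WT replicates 2 and 3 and 5.06 to 5.49 in IL5-Tg libraries (mean log2(CPM + 1)). Without WT replicate 2 the ribosomal list had a mean of -0.02 (camera adjusted p = 0.614). Without WT replicate 3 the camera adjusted p was 0.714 for both the active tissue eosinophil markers and the immediate early genes.

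No camera call was made for type I interferon response (adjusted p = 0.423), interferon gamma response (0.873), adhesion and migration receptors (0.0737), matrix remodelling and fibrosis (0.155), nuclear oxidative phosphorylation subunits (0.725), unfolded protein and integrated stress response (0.860) and apoptosis effectors (0.101). For the type I interferon list the camera direction was down while the mean log2 fold change was 0.03 and the median -0.02. For interferon gamma the direction was up with a mean of 0.14 and a median of -0.11. Without WT replicate 3 that list was called higher, at a mean of 0.78 (camera adjusted p = 0.0273). For oxidative phosphorylation the direction was down with a mean of -0.02 and a median of 0.00259. In the matrix list Plaur, the urokinase receptor gene, rose from 149 ± 46.3 to 563 ± 141 CPM (edgeR adjusted p = 0.0375) while Thbs1 fell.

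Markers of other cell types were present in the sorted samples and differed between libraries. Fibroblast markers had a mean log2(CPM + 1) of 7.07 to 7.54 in WT replicates 1 and 2, 1.92 in WT replicate 3 and 6.66 to 7.99 in the IL5-Tg libraries. Col1a1 was at 500, 751 and 4.82 CPM in the 3 WT libraries. Fibroblast markers were called higher in IL5-Tg libraries (camera adjusted p = 0.0251, and adjusted p = 0.627 with an estimated correlation), as were cell cycle genes (adjusted p = 0.00015, and adjusted p = 0.627 with an estimated correlation), but without WT replicate 3 the camera adjusted p was 0.714 and 0.340. For fibroblast markers it was 0.0536 without WT replicate 2 and 0.0525 without IL5-Tg replicate 4. None of the 9 fibroblast or 34 cell cycle members passed by edgeR. Muscle fibre markers were higher (camera adjusted p = 0.00152, and adjusted p = 0.585 with an estimated correlation), also without WT replicate 3 (adjusted p = 0.00500), and 0 of 13 members passed, Atp2a1 being at 2.16 (edgeR adjusted p = 0.148). Mast cell and basophil markers were lower (camera adjusted p = 0.00075, and adjusted p = 0.394 with an estimated correlation). Hdc was the 1 of 7 members that passed, and the median log2 fold change was -2.29. When adjusted over the list alone, 3 were lower and 1 was higher. The mast cell protease gene Mcpt4 was at -2.75 (edgeR adjusted p = 0.462), and Gata2, at 1.57, was the 1 member with a positive log2 fold change.

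Camera made no call for markers of macrophages and monocytes (adjusted p = 0.479), neutrophils (0.278), dendritic cells with class II genes (0.370), muscle progenitors (0.329), endothelium (0.0944) and NK and innate lymphoid cells (0.815). No call does not mean that their RNA was absent. Macrophage and monocyte markers were at 7.78, 8.09 and 6.47 in WT replicates 1, 2 and 3 and 7.26 to 8.07 in IL5-Tg libraries (mean log2(CPM + 1)). The macrophage gene C1qa was at 373, 674 and 68.4 CPM in WT replicates 1, 2 and 3 and 350 to 776 CPM in IL5-Tg libraries. Whether such RNA holds part of a changed gene's level was not tested. The neutrophil list held Ngp, which rose, and Retnlg, which fell. Of its 9 tested members 2 had a positive log2 fold change, and the median was -0.69. When adjusted over the list alone, 1 was higher and 4 were lower. Without WT replicate 3 the list was lower (camera adjusted p = 5.8e-07). Too few members of the T cell, B cell, erythroid and immature granulocyte lists passed the count filter for a test. Their mean log2(CPM + 1) was 0.520 and 0.530 for T cells, 0.514 and 0.534 for B cells, 0.318 and 0.625 for erythroid cells and 1.39 and 1.16 for immature granulocytes in WT and IL5-Tg libraries. Sex-linked genes stood at 3.06 ± 0.506 (SD, n = 3) and 2.68 ± 0.243 (SD, n = 4; exact p = 0.229). That mean joins Xist and Tsix with Y-linked genes, which differ between sexes in opposite directions, so it cannot show whether sexes were balanced. The Y-linked genes Ddx3y and Eif2s3y had reads in every library, at 47.6 to 187 CPM and 11.3 to 79.0 CPM. Mean levels per library were also compared for 31 lists with a two-sided exact permutation test. Granule proteins, IL-5 and STAT5 targets, lipid mediator genes, glycolysis genes and mast cell markers each gave exact p = 0.0286, the smallest that 35 splits allow, and an adjusted p of 0.177, so 0 of 31 lists passed. Of the 27 lists tested by camera 14 were called, 9 higher and 5 lower, 0 of them with an estimated correlation and 2 by fry, the granule and lipid mediator lists, and 12 of the 35 splits of the libraries called at least as many.

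**Figure D2:**
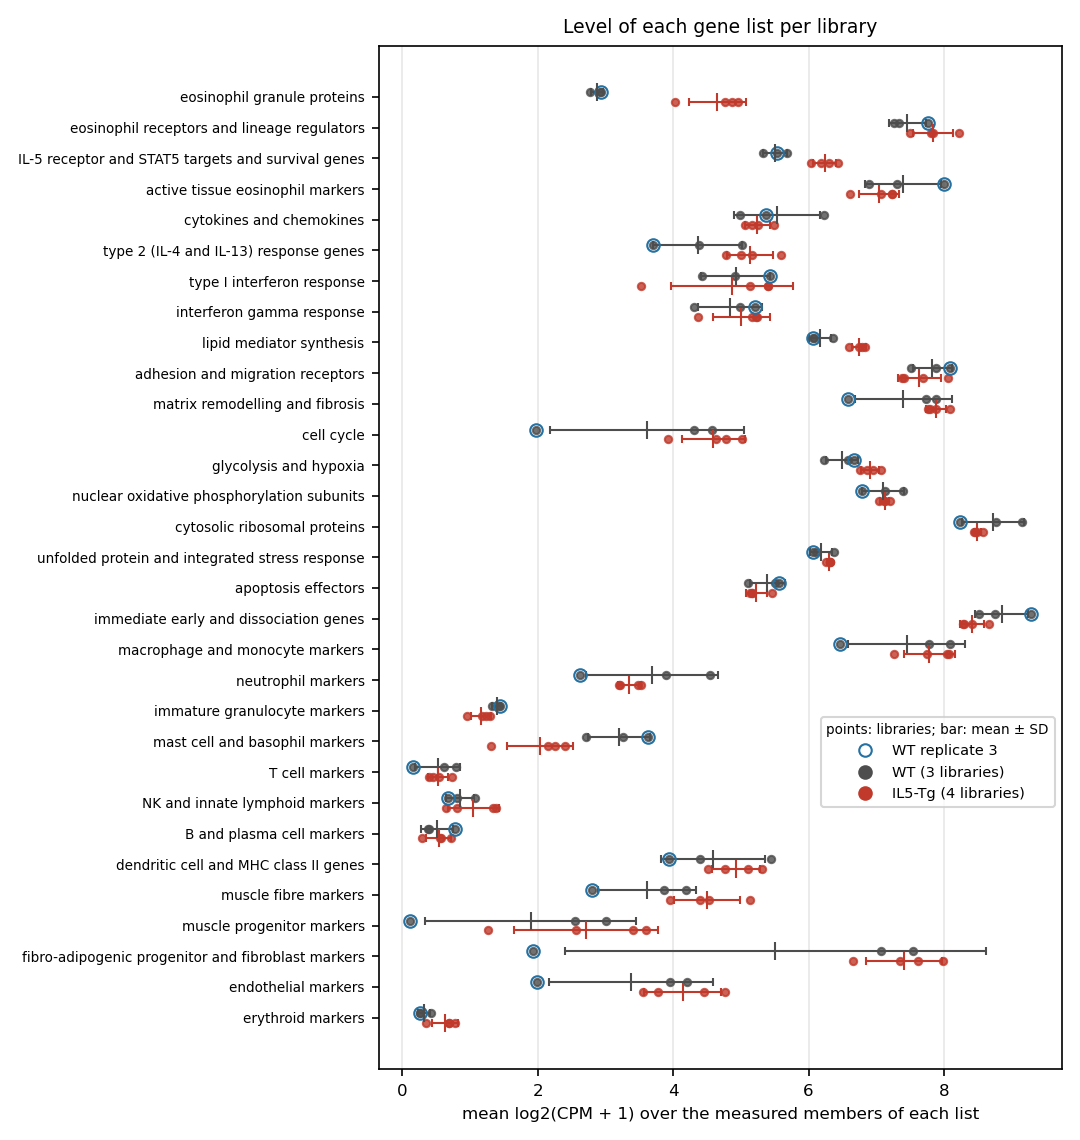
Level of each gene list in each library, as the mean log2(CPM + 1) of its measured members on the horizontal axis. Points are libraries (3 WT in grey, 4 IL5-Tg in red), bars give the mean and SD, and the blue ring marks WT replicate 3, which lies at 1.92 for fibroblast markers where the other libraries lie between 6.66 and 7.99.

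The libraries also differed in how their low counts were distributed. The most common low count of a gene was 5, 8 and 12 reads in WT replicates 1, 2 and 3 and 1, 1, 1 and 4 reads in IL5-Tg replicates 1, 2, 3 and 4 (exact p = 0.0286, adjusted p = 0.0857 over 6 measures, two-sided permutation test). Genes detected numbered 12483 ± 1487 (SD, n = 3) in WT and 14113.5 ± 351 (SD, n = 4) in IL5-Tg libraries (exact p = 0.0571, adjusted p = 0.0857). Reads assigned to no gene made up 16.8% ± 1.33 (SD, n = 3) in WT and 11.0% ± 1.87 (SD, n = 4) in IL5-Tg libraries (exact p = 0.0286, adjusted p = 0.0857). Correlations across genes were 0.959 to 0.973 between IL5-Tg libraries and 0.861 to 0.920 between WT libraries, and 0.857 to 0.950 (median 0.934) between a WT and an IL5-Tg library, where genes are not independent replicates. WT libraries were thus no more alike than libraries of different genotypes.

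**Figure D3:**
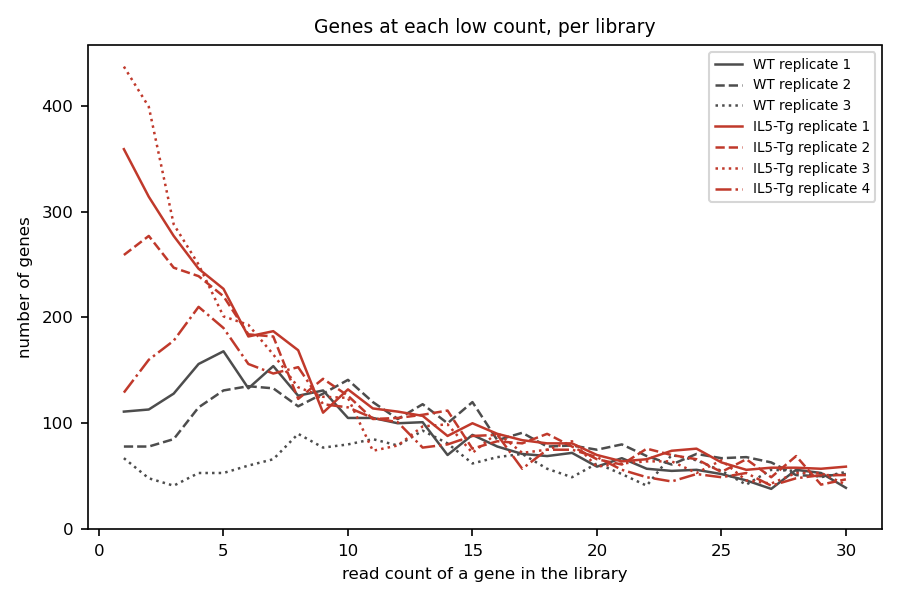
Number of genes (vertical axis) at each read count from 1 to 30 (horizontal axis), 1 line per library, WT in grey and IL5-Tg in red. WT replicate 3 held 115 genes at 1 or 2 reads, and IL5-Tg replicate 3 held 836.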

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

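All tests of explanations in this part were chosen after the results they concern were seen. In the IL5-Tg group of 4 libraries, 9 of 116 values had 1 library far from the other 3 by Dixon's test, which by chance happens in about 1 of 20 groups.

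IL5-Tg replicate 3 was low for the type I interferon list, at 3.53 against 5.13 to 5.40 in the other IL5-Tg libraries, and for the interferon gamma list, at 4.37 against 5.17 to 5.24 (mean log2(CPM + 1)). IL5-Tg replicate 2 was low for the unfolded protein and integrated stress response list, at 6.26 against 6.31 to 6.32, and high for apoptosis effectors, at 5.45 against 5.13 to 5.17. IL5-Tg replicate 4 was high for Ngp, at 33.5 CPM against 26.3 to 26.8, and for Cdkn2a, at 77.4 CPM against 70.3 to 71.2. It was low for Ear1, at 49.3 CPM against 91.3 to 99.7, and for Ear6, at 17.7 CPM against 31.7 to 34.0. It was also lowest for several raised genes that did not pass Dixon's test. Among them were Car4, at 232 CPM against 449 to 511, and Prg2, at 423 CPM against 692 to 1122. It was not lowest for Il5, Enah or Cacna2d2, and it was highest for Retnla. Its most common low count was 4 reads, against 1 read in the other 3.

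The first pattern weighed is the set of 51 changed genes. Of the 35 splits of the libraries into 3 and 4, 1 gave as many changed genes, 1 as many of the 42 higher and 1 as many of the 9 lower genes. In each case it was the real split, and the highest count in the others was 0. Chance in the grouping is thus unlikely but cannot be excluded. With 35 splits the smallest possible exact p is 0.0286, and all the other splits mix the genotypes, which raises the spread within their groups. With the level of macrophage, fibroblast and endothelial markers as a covariate, 51 of 51 calls were kept. That level was 6.76, 6.83 and 4.07 in WT replicates 1, 2 and 3 and 6.16 to 7.22 in IL5-Tg libraries (mean log2(CPM + 1)). It overlapped between the groups, so it could hardly remove calls between them. The combined amount of these markers thus did not follow genotype, but RNA of a single cell type or a changed state of those cells was not tested. Mast cell and basophil markers, which include Hdc, were not part of that level. They did not overlap between the groups, at 2.71 to 3.62 in WT and 1.32 to 2.40 in IL5-Tg libraries. Muscle fibre markers were not part of it either and overlapped, at 2.80 to 4.19 in WT and 3.96 to 5.13 in IL5-Tg libraries. Fewer captured molecules in the WT libraries are a further candidate, because the most common low count was 5 to 12 reads in every WT library and 1 to 4 in every IL5-Tg library. Division of counts by it kept 42 of the 42 higher genes but leaves the proportions within a library as they were. Thinning all libraries to the same number of molecules kept 16 of the 42, with 37 tested, but costs power whatever the cause. For the 21 tested genes that lost their call the median log2 fold change was 2.24 before and 2.18 after, and the median SE rose from 0.357 to 0.640. Neither decides. A difference between genotypes stays open as a hypothesis, as do differences in housing, age or sort, which the labels do not give. For the number of camera calls chance is not even unlikely, since 12 of 35 splits gave at least 14 lists and the highest gave 18.

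The second pattern is the low level of other cells' transcripts in WT replicate 3. A low number of captured molecules could lose transcripts at random, but the 6 fibroblast genes with at least 50 CPM in the other WT libraries had a median log2 ratio of -6.79 in that library, lower than all 10000 random lists of genes of like abundance, whose lowest median was -3.15. The sort took CD45-positive, SiglecF-positive cells, a gate that should remove fibroblasts, so how their RNA reached the other libraries is not known. A difference in how well the sort removed other cells stays open and was not tested apart from the pattern itself. The list of eosinophil receptors and lineage regulators was at 7.77 in WT replicate 3, against 7.34 and 7.27 in WT replicates 1 and 2 (mean log2(CPM + 1)). That goes with such a difference, but a smaller share of other RNA raises this level by itself, so it is no separate test. No biological explanation was tested, because the design names none within WT.

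The third pattern is the Il5 RNA in sorted IL5-Tg cells. T cells, which the sort excluded by CD3e, would bring their own abundant transcripts, but Cd3d, Cd3e and Cd3g together reached at most 0.457% of the Il5 level in an IL5-Tg library. Their reads numbered 8 to 17 per IL5-Tg library, so a few T cells with a very active transgene are not argued against. Innate lymphoid cells, a known source of IL-5, should mostly be left out by a sort of SiglecF-positive cells that also removed NK1-positive cells. The counts do not settle it, and they cannot be told apart, because the NK and innate lymphoid list differed by only 0.194 between the groups, with overlapping libraries and members near the floor, and Il7r overlapped too, at 14.1 to 23.4 CPM in IL5-Tg libraries and 14.4, 6.97 and 0.378 CPM in WT replicates 1, 2 and 3 (edgeR adjusted p = 0.755). Transcription of the transgene in the eosinophils themselves may be a source and was not tested, nor was carry-over of transgene DNA.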

How the results depend on the processing

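The other-cell covariate, division by the most common low count, this division followed by thinning to equal molecule numbers, mean CPM of at least 10 and the newer edgeR fit were chosen after seeing the data. Those of the 51 changed genes that an alternative tested kept their sign in each of the 24. Thbs1 and Pgam1 each lost their call in 12 of them, Retnlg in 10, Cdkn2a in 9 and Il5 in 3. The counts of changed, higher and lower genes were 51, 42 and 9. They were 225, 141 and 84 by DESeq2 (16 adjusted p missing), 28, 26 and 2 with glmTreat, 113, 91 and 22 with the covariate, 100, 72 and 28 after division, 20, 17 and 3 after division and thinning (19 of the 51 kept, 46 tested), and 97, 70 and 27 with the newer edgeR fit. By limma-voom 32 changed and 24 were higher against 8 lower. Without a count filter 16 of 72 calls were lower, and with mean CPM of at least 10, 14 of 61. The share of higher calls was 82.4%, against 62.7% by DESeq2, 72.0% after division and 72.2% with the newer fit. Leaving out 1 library gave 16 to 97 changed, 14 to 79 higher and 1 to 31 lower genes, and 30 were higher against 31 lower without WT replicate 2. Of the 51 calls, 16, 29 and 50 were kept without WT replicates 1, 2 and 3, and 16, 16, 16 and 29 without IL5-Tg replicates 1, 2, 3 and 4. The cause was not tested, except that glmTreat asks for a larger change and that thinning to equal molecule numbers raised the SE of the higher genes whose calls ended. The count depends on which library is left out.

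Camera lists numbered 14, and 11 to 17 under the other settings of the counts, but 0 with an estimated correlation and 2 by fry. DESeq2, glmTreat and the newer edgeR fit gave no list value. Muscle progenitor markers turned to -1.19 (camera adjusted p = 0.00386, the lowest of a range up to 0.977) with the title start as a block, and the type I interferon list to 0.31 (camera adjusted p = 0.0394, in a range from 0.0139 to 0.960) without IL5-Tg replicate 3, with values from -0.16 to 0.39 over the left-out libraries. The cause was not tested. The levels of 0 of 31 lists passed with either other pseudocount or with raw library totals, which shows no stability, since the smallest exact p of 0.0286 nearly fixes that count.

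No paired analysis was possible because the labels give no replicate numbers and name no pairs. Some sample titles share a start across genotypes, and a fit with that start as a block was run as a hint only, since its meaning is not given. Only WT replicate 1 with IL5-Tg replicate 3, and WT replicate 2 with IL5-Tg replicate 4, share a start across genotypes. Each start of the remaining libraries holds a single genotype, so the genotype difference in the blocked fit rests on the libraries just named. The blocked fit gave 52 calls, 32 of them among the 51. It had 501 genes with an unadjusted edgeR p under 0.05, against 1123 in the main fit. Depth limits low genes most in the WT libraries, where 1 captured molecule may stand for 5 to 12 reads.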

Other observations

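The tests of this part, and the genes it names, were chosen after their values were seen. Further changed genes included receptors that couple to G proteins. The adenosine receptors Adora2a and Adora2b rose from 67.1 ± 26.1 to 330 ± 73.5 CPM and from 11.6 ± 5.01 to 49.2 ± 9.90 CPM (SD, n = 3 and 4; edgeR adjusted p = 0.0172 and 0.0478). The thrombin receptor gene F2r rose from 11.0 ± 3.91 to 83.5 ± 7.71 CPM (edgeR adjusted p = 0.00311). With Adra2a and Ltb4r2 these make 5 of the 42 higher genes, and no enrichment was tested. Il10ra, a subunit of the IL-10 receptor, rose from 64.3 ± 2.93 to 221 ± 51.4 CPM (edgeR adjusted p = 0.0172).

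Other changed genes, not a full list, included the growth factor gene Hbegf (log2 fold change 2.24), the semaphorin Sema4a (1.96), the membrane serine protease gene St14 (2.22) and Tmem119 (2.36), all of which rose. The transglutaminase gene Tgm1 rose by 2.89, the aldolase gene Aldoc by 2.75 and the transcriptional regulator Cited2 by 1.66. The cell cycle inhibitor gene Cdkn2b rose by 3.51, from 1.59 ± 1.03 to 17.8 ± 3.10 CPM (SD, n = 3 and 4; edgeR adjusted p = 0.0224).

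Some changed genes were neighbours on mm10 (GENCODE vM21). Cdkn2a and Cdkn2b lie on chromosome 4 at 89274471 to 89294653 and 89306299 to 89311039. Upp1 and Abca13 lie 55.8 kb apart on chromosome 11, Tgm1 and Ltb4r2 47.5 kb apart on chromosome 14, and Retnla and Retnlg 28.2 kb apart on chromosome 16. A hypothesis is that some changes are shared by neighbouring genes. Among the 49 changed genes with a position there were 4 pairs within 100 kb, where 10000 random sets of as many tested genes held 0.380 on average (permutation p = 0.0014). The pairs were seen before the test, and the sets were not matched on expression or gene family. Chance placement is therefore not excluded. In 3 of the 4 pairs both genes rose, and in the Retnla and Retnlg pair they moved in opposite directions. Whether a shared regulatory region is the cause was not tested.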
